A study of Homo sapiens with 4 samples.

How the data were processed

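RNA from 4 OVCAR-3 libraries was compared, 2 labelled shControl and 2 labelled shSPTLC2. Groups and replicate numbers were taken from the sample titles. The submitters deposited 2 tables with 58735 genes each, 1 of counts and 1 of FPKM, each with 1 column per library. Per the submitters' processing notes, HISAT2, StringTie and SAMtools and the genome build hg38 were used, without versions or order. The tool that made the counts, its settings and its use of strand are not given in the sources used here. Per the labels' protocols, total RNA was purified with TRIzol and lithium chloride from ground tissue, although the labels name a cell line, and this was not resolved from the sources used here. Per the same protocols libraries were made with a kit that, as named there, does not mark strand, so reads of overlapping or antisense genes cannot be told apart. The deposited count values were whole numbers and not normalized. Each deposited FPKM value equalled the count divided by the deposited gene length and by 1 constant per library, within 3.2e-06% on genes with more than 20 counts, and that constant was 99.2% to 101.55% of the library total. All 58735 Ensembl identifiers were found in GENCODE release 29, which supplied transcript GC content and length. The deposited gene symbols held 27 that a spreadsheet had turned into dates, and these were replaced through their Ensembl identifiers.

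Total counts ranged from 14560895 to 15041377 per library, with 19810 to 20735 genes detected and 5.01% to 6.57% of counts from mitochondrial genes. The 2 libraries of a group differed by 4.16 (shControl) and 5.48 (shSPTLC2) chi-square units per degree of freedom over genes with at least 20 counts in the pair, so neither pair was a duplicate, and libraries of different groups by 8.63 to 21.3. The common biological coefficient of variation was 6.42%, and 5.37% after the correction described here.

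The designed test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with filterByExpr defaults (14062 genes kept), TMM factors (0.987 to 1.01), robust dispersion estimates and no covariate. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The SE of an edgeR log2 fold change was not estimated directly but taken as its absolute value divided by the square root of the F statistic. Confidence intervals were built from this SE and the t distribution, at the 0.95 level. Levels in CPM are counts scaled to TMM-adjusted library sizes. For a gene with 0 counts the limit was set at 3 counts of a library's total, which covers counting error only.

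The comparison of 2 against 2 libraries was the only one that the labels imply. The test, the gene lists, the rule for naming genes and the other settings to be tried were fixed before the data were examined. There were 36 gene lists with 956 symbols, of which 953 were matched to the tables, and 34 lists had at least 5 tested members. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the 34 lists, and again with a correlation estimated per list and with fry. Camera compares a list with all other genes; the directional p of fry tests whether its genes move on balance one way and the mixed p whether they change in either direction. At the preset correlation 18 lists were called, 15 lower and 3 higher, and after the GC and length correction 12, 11 lower and 1 higher, of which 10 were called in both. With an estimated correlation camera called 0 lists, with 3 at an unadjusted p under 0.05, and after the correction also 0, with 2 at an unadjusted p under 0.05. That form of camera takes its degrees of freedom from the 4 libraries, so an adjusted p under 0.05 was hard to reach. A call lost there does not by itself show that correlated genes had made it. For the unfolded protein response and cholesterol lists the estimated correlation was −0.04 and −0.02, below the preset 0.01. Among other called lists it was 0.895 (mitochondrially encoded), 0.134 (hypoxia), 0.128 (epithelial), 0.097 (apoptosis), 0.0938 (p53), 0.0795 (ribosomal), 0.0772 (G2/M) and 0.0617 (JAK-STAT3). These values exceed the preset, so correlated genes may have helped to make those calls. The remaining called lists lay below the preset. All these estimates rest on the same 4 libraries. Fry, run without the GC and length correction only, called 9 lists by direction and 28 in either direction. The unfolded protein response and cholesterol lists were among those called by direction in fry (adjusted p = 0.0287 and 0.034). Median and test differed in sign for the Notch, NRF2, drug transport and HEK293-like lists, and mean and test for the interferon, Notch and HEK293-like lists, none of them called. After the correction the median changed sign for the ceramide synthesis, EGFR family, ovarian lineage, G1/S, interferon, NRF2, drug transport and fibroblast lists, and the direction in camera for the ceramide synthesis, ERK, ovarian lineage and Notch lists, none of them called before or after.

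Genes were named by this rule. SPTLC2 and ZDHHC15 were named as hairpin targets and EGFR and STAT3 from the title. The 12 higher and 12 lower protein-coding genes with the largest change were named among called genes of at least 5 CPM in the higher group whose groups did not overlap. Up to 5 abundant genes per direction with at least 2-fold change and up to 4 called members per list (up to 2 by abundance where none was called) could also be named. SPTY2D1, given in the closing section, is outside the rule and was chosen after its values were seen. Exons of ATP7A, CCND1, CISH, DDIT3, ENG, EVA1B, JUNB, MVK, PLEKHG5, SHC1, SLC16A3, SLC7A11, SREBF1, TAP1 and ZGPAT overlap those of another tested gene, so their counts are less certain. The values of 1 member of the cholesterol synthesis list, which counts in the list's totals and tests, are not reported here.

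A correction for GC content and transcript length was added after seeing the data. For each library a smooth trend (mgcv 1.9.3, 8 basis functions) of the deviation in log2 CPM was fitted on the GC content and log2 length of the longest transcript and entered as an offset, for 14055 of 14062 genes with both values. The other settings were different scaling factors, DESeq2 1.42.0 (its independent filtering leaves genes of low count without an adjusted p), limma-voom, other count filters, fits without robust estimation, a replicate block, log2 of FPKM plus 1 or plus 0.1, protein-coding genes alone, an adjusted p under 0.01 and each library left out in turn. The exact test of edgeR and DESeq2 without independent filtering were added after seeing the data. On simulated counts for 14062 genes with 200 changed genes and no trend, edgeR called 53% of genes changed by log2 0.5 and 82% of those changed by log2 1, with 11 false calls. With the measured GC and length trend added, false calls were 325 without the correction and 18 with it. The trend was added and removed by the same kind of fit, so this drop was built in. It does not show that the correction suits the real libraries.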

Results

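Gene expression was measured by RNA sequencing in OVCAR-3, an established human line of ovarian carcinoma cells. The labels place 2 libraries in a group that received a control short hairpin RNA (shControl) and 2 in a group that received a hairpin against SPTLC2 (shSPTLC2). SPTLC2 encodes a catalytic subunit of serine palmitoyltransferase, the enzyme that starts sphingolipid synthesis. The series title names EGFR and STAT3, so the comparison of the 2 groups bears on the RNA of these genes and of the pathways around them. The treatment protocol names ZDHHC15 as the hairpin target instead, with harvest 36 h after transient transfection, whereas the series text speaks of stable knockdown of SPTLC2. The libraries held 14874915 and 15041377 counts in shControl and 14611842 and 14560895 counts in shSPTLC2. Nothing in the labels says that the libraries of a group came from separate cultures. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. Those of camera at the preset correlation set the genes of a list against all other genes. They rest on the spread across genes, which are not independent replicates, and can be very small with 2 libraries per group. Fold changes are given as log2 of shSPTLC2 over shControl ± SE, and levels as normalised counts (CPM) ± SD with n = 2 per group.

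SPTLC2 RNA was not lower in the libraries labelled shSPTLC2. SPTLC2 (ENSG00000100596, hg38 chromosome 14, 77505997 to 77616773, minus strand, protein-coding) had 619 and 667 counts in the shControl libraries and 711 and 655 counts in those labelled shSPTLC2. Its level was 43.5 ± 1.84 CPM in shControl and 46.4 ± 2.47 CPM in the libraries labelled shSPTLC2. The log2 fold change was 0.09 ± 0.10 (edgeR quasi-likelihood test, adjusted p = 0.581), with a 95% interval from −0.11 to 0.29. With a correction for transcript GC content and length, chosen after seeing the data, it was −0.03 (adjusted p = 0.921), with an interval from −0.21 to 0.16. ZDHHC15 had 0 counts in all 4 libraries, which allows at most 0.206 CPM in any of them (3 counts, counting error only). Because SPTLC2 RNA goes against the label, every direction reported here is that of libraries labelled shSPTLC2, not of cells shown to have lost SPTLC2 RNA.

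**Figure D1:**
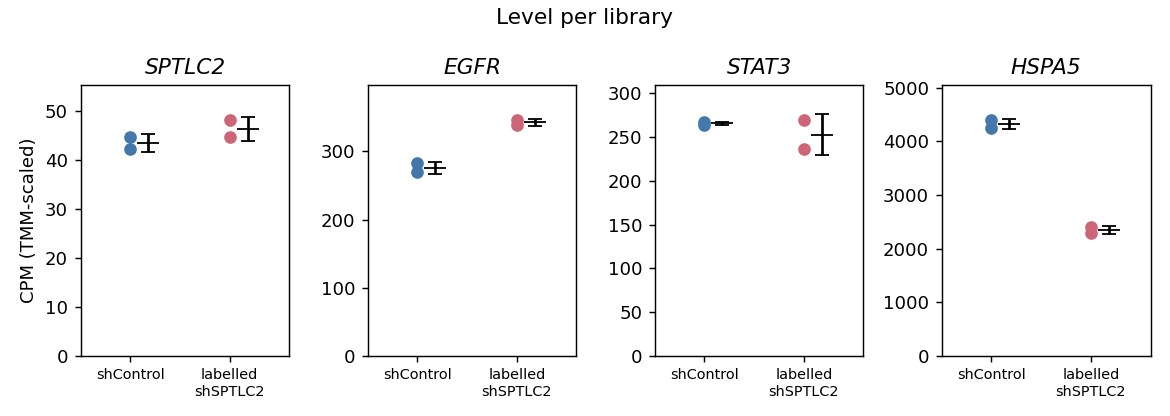
Levels in CPM (vertical axes from 0) of SPTLC2, EGFR, STAT3 and HSPA5 in each library (points), with the group mean ± SD (black bar, n = 2) beside them. SPTLC2 was at 43.5 CPM in shControl and 46.4 CPM in the libraries labelled shSPTLC2, while HSPA5 was at 4323 and 2343 CPM.

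EGFR RNA rose and STAT3 RNA did not pass the test in the libraries labelled shSPTLC2. EGFR (ENSG00000146648, chromosome 7, 55019021 to 55211628, plus strand), the receptor of epidermal growth factor, was at 276 ± 8.77 CPM in shControl and 343 ± 4.52 CPM in the libraries labelled shSPTLC2. Its log2 fold change was 0.31 ± 0.06 (edgeR, adjusted p = 0.00190) and 0.24 ± 0.05 after the GC and length correction (adjusted p = 0.00332). STAT3 (ENSG00000168610, chromosome 17, 42313324 to 42388568, minus strand), a transcription factor activated by cytokine receptors, was at 266 ± 2.15 and 253 ± 23.2 CPM, a log2 fold change of −0.07 ± 0.06 (adjusted p = 0.518, 95% interval −0.21 to 0.06). RNA levels do not measure the phosphorylation of either protein.

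Genes around these signalling pathways moved in both directions. Of 23 tested EGFR family ligands and adaptors, 2 rose and 1 fell over all genes tested, and likewise 2 and 1 adjusted over the list alone. This share was near that of all tested genes, of which 1723 of 14062 were called. The adaptor SHC1 fell by 0.49 on the log2 scale (SE 0.07, adjusted p = 1.9e-04), and the list had a median of 0.08 (camera adjusted p = 0.256). After the correction 1 rose and 1 fell (median −0.01), and with each library left out the median was 0.02 to 0.10. Of 22 ERK output genes, 1 rose and 5 fell (1 and 6 adjusted over the list alone), with a median of −0.05 (camera adjusted p = 0.280). After the correction 1 rose and 1 fell, with a median of −0.00, and the uncorrected median was −0.12 to 0.02 with each library left out. The cyclin gene CCND1 rose by 0.29 ± 0.06 (adjusted p = 0.00635), and the immediate early gene IER2 fell by 0.53 (SE 0.10, adjusted p = 0.00193, and −0.29 after the correction). Of 33 JAK-STAT3 components and targets, 4 rose and 9 fell (5 and 13 adjusted over the list alone). JUNB fell from 150 ± 13.5 to 88.6 ± 11.4 CPM, the kinase gene PIM3 from 196 ± 9.64 to 120 ± 15.9 CPM, and the cytokine gene LIF from 52.9 ± 0.922 to 32.6 ± 2.53 CPM. After the correction JUNB was at −0.46 and PIM3 at −0.40, from −0.75 and −0.70. As a set these genes were called lower (median −0.13, camera adjusted p = 0.0105), with an adjusted p = 0.468 with an estimated correlation. The call ended after the GC and length correction (adjusted p = 0.0575, median −0.00, 1 member higher and 6 lower) and without shControl replicate 1 (median −0.07, adjusted p = 0.237), and the median was −0.04 without shSPTLC2 replicate 2. Of 24 PI3K-AKT-mTOR components, EIF4EBP1 alone fell, by 0.32 on the log2 scale (SE 0.08, adjusted p = 0.0180), also 1 adjusted over the list alone. Its call ended after the correction (−0.01), without shControl replicate 1 (−0.30) and without shControl replicate 2 (−0.34), and the list was not called (median 0.06, camera adjusted p = 0.729, and 0.02 after the correction).

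Over all genes, 1723 of 14062 tested genes changed in the libraries labelled shSPTLC2, 549 higher and 1174 lower (edgeR, adjusted p under 0.05). In each of the 1723 genes both libraries of a group lay on one side of both libraries of the other, as they did in 56.3% of all tested genes, against 33.3% by chance. For called genes this separation is close to built in. The 33.3% holds for libraries that can be exchanged, whereas a trend along GC content can part the groups in many genes at once. The excess is thus no separate evidence for single genes. At least 2-fold changes were called in 43 genes, 17 higher and 26 lower. The calls followed GC content. With the genes ordered by GC content and split into 10 equal parts, the median log2 fold change went from 0.15 in the part with the lowest content to −0.28 in the part with the highest, which held 396 of the 1174 lower calls. Across genes, which are not independent replicates, GC content and log2 fold change had a Spearman correlation of −0.50. After the correction this was −0.01, and 857 genes were called, 240 higher and 617 lower. In the same direction 556 genes were called in both fits, which used the same counts, so some overlap was built in. At least 2-fold changes were then called in 20 genes, 7 higher and 13 lower. The uncorrected count was 576 without shControl replicate 2 and 1084 without shSPTLC2 replicate 2, and the 2-fold count 22 without shControl replicate 2 and 121 without shSPTLC2 replicate 1. The corrected count was 299 without shControl replicate 1 and 304 without shControl replicate 2.

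**Figure D2:**
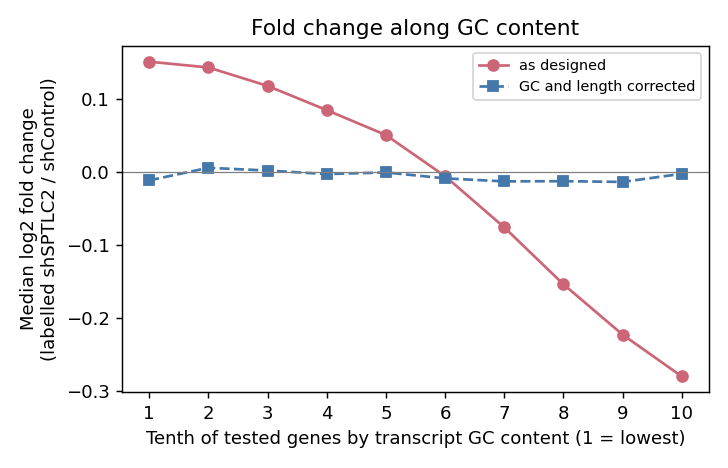
Median log2 fold change (libraries labelled shSPTLC2 over shControl, vertical axis) in 10 equal parts of the tested genes ordered by transcript GC content (horizontal axis), as designed (circles) and with the GC and length correction (squares). The median goes from 0.15 to −0.28 as designed, and after the correction lies between −0.01 and 0.01.

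Many genes of the unfolded protein response, which raise the folding capacity of the endoplasmic reticulum, fell in the libraries labelled shSPTLC2. HSPA5 (ENSG00000044574, chromosome 9, 125234853 to 125241330, minus strand), the main chaperone of that compartment, went from 4323 ± 99.1 to 2343 ± 80.2 CPM, a log2 fold change of −0.88 ± 0.05 (edgeR, adjusted p = 1.2e-08). HERPUD1, a factor of protein degradation at the endoplasmic reticulum, went from 500 ± 18.8 to 273 ± 13.7 CPM (−0.87 ± 0.06, adjusted p = 8.2e-08). SDF2L1 (−0.85 ± 0.11, and −0.55 after the GC and length correction) and the secreted factor MANF (−0.70 ± 0.07) also fell. Of 24 tested members 13 fell and the other 11 were not called, and 16 fell adjusted over the list alone. The list was called lower (median −0.23, camera adjusted p = 4.2e-21), with an adjusted p = 0.144 with an estimated correlation. After the GC and length correction 18 members fell, the median was −0.31, and HSPA5 was at −0.95 (adjusted p = 3.3e-14) and HERPUD1 at −0.91.

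Of 28 tested genes of the integrated stress response, driven by the transcription factor ATF4, 10 fell and 1 rose (11 and 1 adjusted over the list alone). DDIT3, encoding the transcription factor CHOP, went from 35.7 ± 3.12 to 18.9 ± 3.03 CPM (−0.92 ± 0.13, adjusted p = 2.9e-04). PPP1R15A, a phosphatase subunit that reverses the response, fell by 0.82 on the log2 scale (SE 0.10), and DDIT4, an inhibitor of mTOR signalling, by 0.59 (SE 0.09). The cystine transporter gene SLC7A11 rose by 0.41 ± 0.07 (0.22 after the correction). The response genes were called lower as a set (median −0.20, camera adjusted p = 1.4e-04), with an adjusted p = 0.370 with an estimated correlation. After the correction the call held (adjusted p = 0.00600) with a median of −0.05, but not without shControl replicate 1 as well (−0.07, adjusted p = 0.0527). DDIT3 shares exon sequence with neighbouring genes, so its count is less certain. Among 20 immediate early and heat shock genes 7 fell and 3 rose (10 and 3 adjusted over the list alone), with a median of −0.26 (camera adjusted p = 9.7e-04, and adjusted p = 0.370 with an estimated correlation). After the correction 6 fell and 1 rose, with a median of −0.16 (adjusted p = 0.0275), a call that ended without shSPTLC2 replicate 1 (−0.14, adjusted p = 0.0632). ZFP36, an RNA decay factor, went from 43.4 ± 6.16 to 28.9 ± 2.83 CPM (−0.59 ± 0.12, adjusted p = 0.00372).

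**Figure D3:**
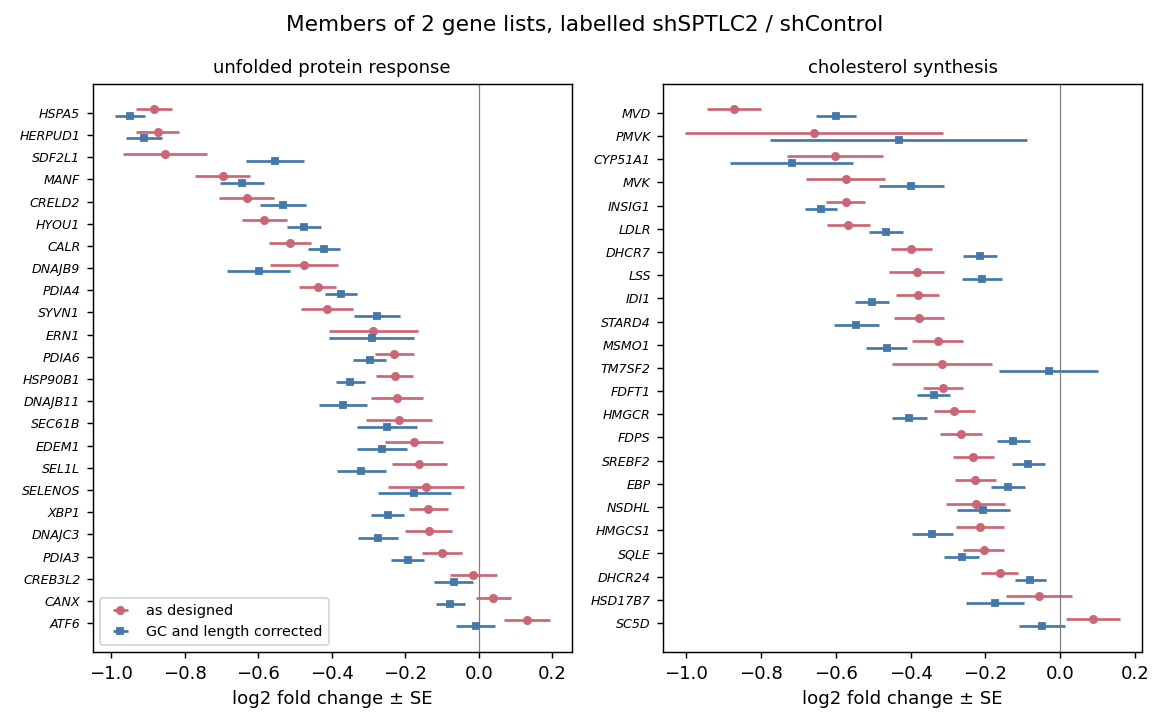
Log2 fold change ± SE (horizontal axes, libraries labelled shSPTLC2 over shControl) of tested members of the unfolded protein response list (left) and the cholesterol synthesis list (right, 1 member not drawn), as designed (circles) and with the GC and length correction (squares). The medians over all tested members are −0.23 and −0.32 as designed, and −0.31 and −0.34 after the correction.

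Many cholesterol synthesis genes fell in the libraries labelled shSPTLC2. MVD (ENSG00000167508, chromosome 16, 88651935 to 88663161, minus strand), an enzyme of the mevalonate pathway, went from 211 ± 11.0 to 115 ± 9.49 CPM (−0.87 ± 0.07, adjusted p = 1.2e-06). MVK, the mevalonate kinase gene, fell by 0.57 on the log2 scale (SE 0.10), and CYP51A1, a sterol demethylase gene, by 0.60 (SE 0.13). Of 24 tested members 19 fell and the other 5 were not called, and 21 fell adjusted over the list alone. The set was called lower (median −0.32, camera adjusted p = 2.5e-21), with an adjusted p = 0.144 with an estimated correlation. After the GC and length correction 15 members fell, the median was −0.34 and MVD was at −0.60 (adjusted p = 7.1e-08). The call of CYP51A1 ended without shControl replicate 2 (log2 fold change −0.42).

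Fatty acid and glycerolipid synthesis genes also fell in part, 7 of 21 (7 lower and 1 higher adjusted over the list alone). FASN, the fatty acid synthase gene, went from 1776 ± 13.3 to 1200 ± 121 CPM (−0.57 ± 0.06, adjusted p = 1.9e-05, and −0.31 after the correction). The acyltransferase gene AGPAT2 fell by 0.48 (SE 0.09) and the regulator SREBF1 by 0.36 (SE 0.07) on the log2 scale, and both calls ended after the correction (−0.17 and −0.11). SREBF1 was at −0.24 without shSPTLC2 replicate 2. Together these genes were called lower (median −0.12, camera adjusted p = 0.00548), with an adjusted p = 0.370 with an estimated correlation. After the correction 7 members were lower and 0 higher, and the set call held (median −0.14, camera adjusted p = 4.6e-04, and 0.420 with an estimated correlation). Serine and one-carbon synthesis genes had 3 of 13 lower and 1 higher (4 and 1 adjusted over the list alone). Their median was −0.11 (camera adjusted p = 0.118) and went from −0.18 to −0.01 with each library left out. PHGDH, the first enzyme of serine synthesis, went from 96.8 ± 5.38 to 72.3 ± 3.79 CPM (−0.42 ± 0.08, adjusted p = 0.00272), and SHMT2 fell by 0.39 (SE 0.06, and −0.24 after the correction). This list was called lower after the correction (adjusted p = 0.0358, median −0.18), with an adjusted p = 0.420 with an estimated correlation. Of the 4 corrected fits with 1 library left out, only that without shControl replicate 2 kept the call (−0.08, adjusted p = 0.0155).

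Genes of the sphingolipid pathway itself moved in both directions. Of 11 tested genes of de novo ceramide synthesis 2 rose and 1 fell (2 and 2 adjusted over the list alone), with a median of 0.05 (camera adjusted p = 0.636). After the GC and length correction 1 rose and 1 fell, and the median and the direction in camera turned (−0.07, adjusted p = 0.804). With each library left out the uncorrected median was −0.01 to 0.10, and the corrected one was 0.08 without shSPTLC2 replicate 1. DEGS1, the desaturase that makes ceramide, went from 91.1 ± 4.03 to 113 ± 5.77 CPM (0.31 ± 0.07, adjusted p = 0.0116). Its call ended without shControl replicate 2 (0.27) and without shSPTLC2 replicate 2 (0.25). Of 34 genes of sphingolipid conversion and turnover 1 rose and 3 fell (1 and 4 adjusted over the list alone). This share was near the 1723 of 14062 called over all tested genes. The median was −0.04 (camera adjusted p = 0.461, and −0.09 to −0.04 with each library left out). The ceramidase gene ACER3 rose by 0.54 ± 0.12 (adjusted p = 0.00869), and after the correction its call ended (0.38, adjusted p = 0.0589). The lysosomal sialidase gene NEU1 fell by 0.36 (SE 0.07, adjusted p = 0.00236, and −0.33 after the correction).

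SRXN1 had the largest fall among called protein-coding genes of at least 5 CPM whose groups did not overlap. SRXN1 (ENSG00000271303, chromosome 20, 646615 to 653370, minus strand), the sulfiredoxin gene, went from 17.5 ± 2.16 to 7.74 ± 1.21 CPM (−1.17 ± 0.17, adjusted p = 4.9e-04). CCDC9 went from 48.8 ± 3.50 to 22.6 ± 2.05 CPM (−1.11 ± 0.11, adjusted p = 1.2e-05), and PLEKHH3 from 77.6 ± 7.89 to 39.6 ± 5.53 CPM (−0.97 ± 0.10). BBC3, encoding the cell death protein PUMA, went from 17.9 ± 1.63 to 8.52 ± 1.06 CPM (−1.07 ± 0.16). These 4 genes were also called after the GC and length correction and with each library left out. The other falls were in CISH, MISP3, IFNL1, ZGPAT, PLEKHG5, JOSD2, MFSD14A and EVA1B, and the 12 lay between −1.17 and −0.95. The 12 largest rises lay between 0.72 and 1.06, in NEXN, ZNF780A, L3MBTL1, ZFP30, DPH6, ZNF480, OLR1, CEP162, GABRA3, ARHGAP28, CFAP44 and C6orf203, with at most 11.8 CPM. ZFP30, a zinc finger gene, went from 6.39 ± 0.0757 to 11.8 ± 1.54 CPM (0.88 ± 0.19, adjusted p = 0.00632) and alone among these risers was called after the correction and with each library left out. After the correction 3 of the 12 rises and 7 of the 12 falls were called, with EVA1B at −0.63 and JOSD2 at −0.64. Of the 24 calls, 9 ended without shControl replicate 1, 15 without shControl replicate 2, 7 without shSPTLC2 replicate 1 and 5 without shSPTLC2 replicate 2. Without shControl replicate 2, GABRA3 was at 0.51, ZGPAT at −0.66 and MFSD14A at −0.64, and MFSD14A was at −1.51 without shSPTLC2 replicate 1 and −0.58 without shSPTLC2 replicate 2.

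Cell cycle genes moved in both directions. Of 36 G1/S genes 5 rose and 7 fell (6 and 7 adjusted over the list alone), with a median of −0.01 (camera adjusted p = 0.572, and −0.01 to 0.01 with each library left out). After the correction 1 rose and 4 fell (median 0.00). CDKN1A, encoding the cell cycle inhibitor p21, went from 197 ± 9.20 to 134 ± 11.2 CPM (−0.55 ± 0.07, adjusted p = 1.3e-04, and −0.37 after the correction), and the transcription factor gene E2F1 fell by 0.62 (SE 0.10, and −0.37 after the correction). Of 38 G2/M genes 10 rose and 1 fell (11 and 3 adjusted over the list alone), with the spindle gene ASPM from 258 ± 6.90 to 330 ± 17.7 CPM (0.35 ± 0.06, adjusted p = 0.00110, and 0.17 after the correction, adjusted p = 0.0371). The G2/M list was called higher (median 0.10, camera adjusted p = 0.0197), with an adjusted p = 0.468 with an estimated correlation. The call ended after the correction (0.06, adjusted p = 0.454, 1 member higher and 2 lower), without shControl replicate 2 (0.06, adjusted p = 0.0550) and without shSPTLC2 replicate 2 (0.08, adjusted p = 0.0659).

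Some apoptosis regulators and p53 target genes fell. Of 33 apoptosis regulators 7 fell and 1 rose (7 and 1 adjusted over the list alone), among them the pore-forming gene BAK1 from 70.0 ± 1.70 to 45.6 ± 9.05 CPM (−0.62 ± 0.11, adjusted p = 0.00163). BBC3 and BAK1 promote cell death. HRK, which also promotes it, rose by 0.58 ± 0.15 (adjusted p = 0.0152), a call that ended without shControl replicate 2 (0.55). The regulators were called lower as a set (median −0.07, camera adjusted p = 0.0234), with an adjusted p = 0.468 with an estimated correlation. Of 22 p53 targets 6 fell and 2 rose (8 and 2 adjusted over the list alone), led by BBC3, SESN2 (−0.66 ± 0.13) and CDKN1A. That list was called lower (median −0.15, camera adjusted p = 0.0219), with an adjusted p = 0.468 with an estimated correlation. Both calls held after the correction (adjusted p = 4.6e-04 and 0.0275), with 6 regulators and 3 p53 targets lower and 1 of each higher, but the p53 call not without shSPTLC2 replicate 2 as well (−0.09). The apoptosis median was −0.16 without shSPTLC2 replicate 1. Both calls ended without shControl replicate 1 (−0.05 and −0.22, adjusted p = 0.0840 and 0.0534) and without shSPTLC2 replicate 2 (−0.09 and −0.10, adjusted p = 0.127 and 0.0698).

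Epithelial and mesenchymal genes both held members that fell. Of 20 epithelial markers 2 rose and 5 fell (3 and 8 adjusted over the list alone), with the tight junction gene CLDN4 from 49.2 ± 4.74 to 31.2 ± 0.00505 CPM (−0.66 ± 0.10, adjusted p = 6.9e-04) and CLDN1 higher by 0.44 ± 0.09. Of 28 mesenchymal and invasion markers 6 fell (8 lower and 1 higher adjusted over the list alone), with SNAI1, a repressor of epithelial genes, from 20.9 ± 2.62 to 10.9 ± 1.29 CPM (−0.94 ± 0.15, adjusted p = 9.3e-04). The epithelial list was called lower (median −0.17, camera adjusted p = 0.0292), with an adjusted p = 0.468 with an estimated correlation. The mesenchymal list was called lower too (median −0.14, camera adjusted p = 0.0214), with an adjusted p = 0.370 with an estimated correlation. Both calls ended after the correction (−0.02 and −0.03, adjusted p = 0.850 and 0.168) and without shControl replicate 1 (−0.13 and −0.19, adjusted p = 0.143 and 0.0653) or shSPTLC2 replicate 2 (−0.04 and −0.09, adjusted p = 0.259 and 0.0698), and the epithelial call also without shControl replicate 2 (−0.07, adjusted p = 0.0850), where the mesenchymal median was −0.08. After the correction 2 epithelial markers rose and 2 fell, 4 mesenchymal ones fell, and CLDN4 and SNAI1 were called (−0.49 and −0.75). Of 11 genes of the ovarian serous lineage 1 rose and 2 fell (3 and 2 adjusted over the list alone), with a median of −0.07 (camera adjusted p = 0.729, and −0.10 to 0.00 with each library left out). After the correction 1 rose and 1 fell (median 0.07). The surface antigen gene MSLN fell by 0.43 (SE 0.06, adjusted p = 5.4e-04), a call that ended after the correction (−0.14).

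The hypoxia list was called lower and the list of mitochondrially encoded genes higher before the correction. Of 35 hypoxia and glycolysis genes 7 fell (12 adjusted over the list alone), with the angiogenic factor gene VEGFA from 242 ± 2.65 to 161 ± 1.82 CPM (−0.58 ± 0.06, adjusted p = 1.7e-05, and −0.52 after the correction). The lactate exporter gene SLC16A3 fell by 0.64 (SE 0.10, and −0.39 after the correction). Hypoxia genes were called lower as a set (median −0.16, camera adjusted p = 0.00502), with an adjusted p = 0.468 with an estimated correlation, and its median was −0.10 without shControl replicate 2 and −0.08 without shSPTLC2 replicate 2. After the correction 4 hypoxia genes fell and 1 rose (median −0.07, adjusted p = 0.0409), and of the 4 corrected fits with 1 library left out, only that without shControl replicate 1 kept the call (−0.08, adjusted p = 0.0276). Of 42 nuclear genes of oxidative phosphorylation 7 fell (7 adjusted over the list alone), with COX8A, a subunit of complex IV, from 84.0 ± 0.496 to 54.3 ± 6.42 CPM (−0.63 ± 0.09, adjusted p = 3.6e-04). That list was not called (median −0.02, camera adjusted p = 0.249), and was called lower after the correction (adjusted p = 0.0449, median −0.04), with an adjusted p = 0.420 with an estimated correlation. The uncorrected median was −0.03 to 0.00 with each library left out, and the corrected call ended without shSPTLC2 replicate 1 (adjusted p = 0.0632). Of 15 mitochondrially encoded genes 2 rose (2 adjusted over the list alone), with the ribosomal RNA MT-RNR1 from 915 ± 57.9 to 1189 ± 122 CPM (0.38 ± 0.06, adjusted p = 0.00130). The list was called higher (median 0.17, camera adjusted p = 0.0203), with an adjusted p = 0.697 with an estimated correlation. The call ended after the correction (0.07, adjusted p = 0.301), and with the correction and without shSPTLC2 replicate 2 camera called the list lower (−0.03, adjusted p = 0.0238). It also ended without shControl replicate 2 (0.04, adjusted p = 0.0997) and without shSPTLC2 replicate 2 (0.07, adjusted p = 0.891), and the median was 0.28 without shControl replicate 1 and 0.27 without shSPTLC2 replicate 1.

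The inflammatory, antigen presentation and lysosomal lists were called lower before the correction. Of 26 NF-kB and inflammatory genes 7 fell and 1 rose (12 and 3 adjusted over the list alone). TNFAIP2 went from 229 ± 3.73 to 165 ± 16.8 CPM (−0.48 ± 0.07, and −0.24 after the correction), and the prostaglandin synthase gene PTGS2 rose from 172 ± 11.97 to 231 ± 3.55 CPM (0.42 ± 0.06, adjusted p = 5.8e-04, and 0.27 after the correction). Inflammatory genes were called lower as a set (median −0.21, camera adjusted p = 0.0168), with an adjusted p = 0.370 with an estimated correlation. Of 17 genes of MHC class I antigen presentation 7 fell (7 adjusted over the list alone), with the peptide transporter gene TAP1 at −0.38 ± 0.07 (−0.22 after the correction). That list was called lower (median −0.15, camera adjusted p = 0.00693, median −0.22 without shSPTLC2 replicate 2), with an adjusted p = 0.370 with an estimated correlation. Its HLA members are close copies of each other and their counts are uncertain. Of 29 lysosome and autophagy genes 6 fell (8 lower and 1 higher adjusted over the list alone), with GABARAPL1, an autophagosome gene, from 141 ± 9.84 to 107 ± 0.320 CPM (−0.40 ± 0.07, adjusted p = 0.00172). Lysosome genes were called lower as a set (median −0.09, camera adjusted p = 0.0219), with an adjusted p = 0.370 with an estimated correlation. After the correction 4 inflammatory genes, 4 of antigen presentation and 2 of the lysosome fell, and 1 inflammatory gene rose. All 3 list calls then ended (medians −0.06, −0.07 and −0.02, adjusted p = 0.0513, 0.184 and 0.277), the inflammatory call also without shControl replicate 1 (−0.21, adjusted p = 0.0534) and the lysosomal call without shSPTLC2 replicate 1 (−0.10, adjusted p = 0.0534).

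Some ribosomal protein genes fell. Of 50 tested, 11 fell and 1 rose (12 and 2 adjusted over the list alone), with RPS2 from 2064 ± 49.3 to 1470 ± 157 CPM (−0.49 ± 0.06, adjusted p = 1.1e-04, and −0.32 after the correction). Ribosomal genes were called lower as a set (median −0.05, camera adjusted p = 0.0292, and 0.0358 after the correction), with an adjusted p = 0.484 with an estimated correlation. The call ended without shControl replicate 2 (adjusted p = 0.118) and without shSPTLC2 replicate 1 (adjusted p = 0.199), each with a median of −0.03. After the correction 8 fell and 4 rose, and that call ended without shSPTLC2 replicate 1 (−0.05, adjusted p = 0.0740). Ribosomal protein genes have many processed pseudogenes, and how reads were shared among them is not given in the sources used here.

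Of the markers of other cell types, 3 fibroblast genes passed the test. None of 19 leukocyte markers passed the count filter, the highest at 0.662 CPM. Of 12 endothelial markers 4 were tested, too few for a set test, and edgeR called 0 over all genes tested and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05. ENG was at 24.3 ± 1.22 and 27.1 ± 1.28 CPM (0.16 ± 0.12, adjusted p = 0.411), and was called after the correction (0.42, adjusted p = 0.0287). Of 7 tested fibroblast markers 1 rose and 2 fell, also 1 and 2 adjusted over the list alone (median 0.13, camera adjusted p = 0.729, and 0.05 to 0.21 with each library left out). After the correction 0 were called (median −0.02). COL1A1, a collagen gene, fell by 0.52 (SE 0.10, adjusted p = 0.00310), a call that ended after the correction (−0.31), and MFAP5 rose by 0.49 ± 0.12 (adjusted p = 0.0152), a call that ended after the correction (0.36) and without shControl replicate 2 (0.45). FBLN1 was at 1091 ± 11.6 and 969 ± 23.0 CPM (−0.17 ± 0.05, adjusted p = 0.0317), a call that ended after the correction (−0.02), without shControl replicate 1 (−0.16), without shControl replicate 2 (−0.18) and without shSPTLC2 replicate 1 (−0.15). Of 6 tested markers of the HEK293-like cells used to package viral vectors edgeR called 0 over all genes tested, with 3 at an unadjusted p under 0.05, and 1 rose adjusted over the list alone (median −0.14, camera adjusted p = 0.932, and −0.07 after the correction). NEFH, a neurofilament gene, was at 63.2 ± 0.287 and 75.2 ± 2.28 CPM (0.25 ± 0.08, adjusted p = 0.0505), and was called after the correction (0.42, adjusted p = 6.6e-04).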

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

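The GC and length correction and fits built on it, the exact test of edgeR and DESeq2 without independent filtering were chosen after seeing the data. SPTLC2 was not called in any of 19 alternatives (log2 fold change −0.03 to 0.14), and without each library in turn it was 0.04 to 0.14. The 1723 changed genes became 1097 with DESeq2, 1015 with DESeq2 without independent filtering, 679 at an adjusted p under 0.01 and 857 after the GC and length correction. The 43 genes changed at least 2-fold became 2 with DESeq2, 18 with DESeq2 without independent filtering, 65 with no count filter, 20 after the correction and 101 with the exact test. DESeq2 was run on all 58735 genes, and without independent filtering on the 14062 tested ones, so these 2 settings also differ in their genes. With independent filtering 8409 genes had an adjusted p, among them 2 of the 43 and 1576 of the 1723, so 41 of the 43 could not be called there. On log2 of FPKM, limma called 0 genes, at any fold, with either pseudocount and without a filter, although 3095 (plus 1), 3084 (plus 0.1) and 3324 (plus 1, no filter) genes had an unadjusted p under 0.05 and edgeR had 3859. On the simulated counts without a trend, limma on log2 of FPKM plus 1 made 106 calls and found 79.1% of genes changed by log2 1. Of 162 genes taken by the naming rule and lists, 130 calls ended with limma on log2 of FPKM plus 1. With each library left out, the counts were 576 to 2117 and 22 to 121, where the lone library was assumed to vary like the other group. The 857 genes called after the correction became 444 with DESeq2 and 299 to 1259 with each library left out. The cause of the other shifts was not tested, except that fewer libraries or a stricter threshold were used where stated. A replicate block gave 1538 changed genes and 56 at least 2-fold, and 837 after the correction. The deviations of same-numbered libraries had a correlation across genes of −0.10, with 2 pairs, so the numbers were not taken as pairs. HES4 changed sign after the correction (0.0830, not called), and so did the direction in camera of the epithelial list with the correction and without shControl replicate 1 (median −0.00670) or without shSPTLC2 replicate 2 (−0.0243), neither called. The mitochondrially encoded list, called higher as designed, was called lower with the correction and without shSPTLC2 replicate 2 (median −0.0294, adjusted p = 0.0238). For these the cause was not tested. Of 106 genes taken by the naming rule to which DESeq2 gave an adjusted p, it ended the calls of 13, without independent filtering it ended 37 of 138, and limma-voom ended 5 calls and made 1 among 172 such genes and lists. The unfolded protein response and cholesterol lists were called in 14 of 15 alternatives each, all but the estimated correlation (medians −0.35 to −0.22 and −0.35 to −0.28). With a simulated recovery of 53% at log2 0.5, small changes can be missed in this design. The simulation held 200 changed genes, fewer than the 1723 called, so its recovery need not carry over. Depth and the number of libraries were not varied.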

Other observations

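In this part the GC and length correction with the fits built on it, the tests on SPTY2D1, on GC content and on the spread of SPTLC2 over the libraries, and the limits set for each explanation were chosen after the results were seen, whereas the gene lists and the uncorrected fits with and without each library were not. Some targets of the Wnt and Hippo pathways rose in the libraries labelled shSPTLC2. DKK1, a secreted Wnt inhibitor, went from 12.7 ± 0.631 to 19.8 ± 2.40 CPM (log2 fold change 0.64 ± 0.15, edgeR adjusted p = 0.00853), and F3, the tissue factor gene, from 65.0 ± 1.50 to 88.7 ± 5.42 CPM (0.45 ± 0.08, adjusted p = 0.00193). Of 17 tested members 4 rose, also 4 adjusted over the list alone. The list was called higher (median 0.09, camera adjusted p = 0.0234, and 0.00600 after the GC and length correction with 3 members higher), with an adjusted p = 0.375 with an estimated correlation. The call ended without shControl replicate 1 (0.05, adjusted p = 0.116) and without shSPTLC2 replicate 1 (0.13, adjusted p = 0.0708).

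Interferon response genes split by direction, with 9 higher and 7 lower of 38 tested (11 and 8 adjusted over the list alone) and no list call (median 0.01, camera adjusted p = 0.246). After the correction 5 were higher and 7 lower (median −0.03), and with each library left out the uncorrected median was 0.01 to 0.03. DDX58, the RNA sensor RIG-I, went from 113 ± 5.17 to 154 ± 1.31 CPM (0.45 ± 0.07, edgeR adjusted p = 5.5e-04), and SAMD9L rose by 0.56 ± 0.09, while IFI6 went from 621 ± 37.9 to 459 ± 29.8 CPM (−0.44 ± 0.06, adjusted p = 2.8e-04). Of 24 NRF2 targets 2 rose and 4 fell (2 and 6 adjusted over the list alone), with a median of 0.02 (camera adjusted p = 0.904, and −0.02 to 0.06 with each library left out) and SRXN1 at −1.17. After the correction 2 rose and 3 fell (median −0.00). Of 18 Notch pathway genes HES4 fell by 0.29 (SE 0.07, adjusted p = 0.0140), also 1 adjusted over the list alone, but was at 0.08 after the correction. Its call also ended without shControl replicate 2 (−0.29) and without shSPTLC2 replicate 2 (−0.24), and the list was not called (median 0.00, camera adjusted p = 0.918, −0.10 to 0.01 with each library left out, and 0.05 after the correction). Of 16 drug transport and resistance genes 3 rose, also 3 adjusted over the list alone (median −0.04, camera adjusted p = 0.572, and −0.06 to −0.02 with each library left out). After the correction none rose and 1 fell (median 0.02), and each of the 3 calls ended without at least 1 library. The copper transporter gene ATP7A rose by 0.45 ± 0.10 (adjusted p = 0.00919), a call that ended after the correction (0.29) and without shControl replicate 2 (0.47). Of 14 replication-dependent histone genes edgeR called 0, with 2 at an unadjusted p under 0.05, also 0 adjusted over the list alone (median 0.08, camera adjusted p = 0.636, 0.01 to 0.09 with each library left out, and 0.19 after the correction). HIST1H1C was at 39.0 ± 0.844 and 36.8 ± 0.160 CPM.

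SPTLC2 RNA was not lower in the libraries labelled shSPTLC2. A log2 fold change of −1 or lower hidden by low depth is argued against by the 95% interval, whose lowest bound in the fits with and without the GC and length correction was −0.21. The log2 range of SPTLC2 over all 4 libraries was 0.19. This argues against an exchange of labels between groups that differ by a log2 fold change of −1 or lower in SPTLC2 RNA. An exchange without such a loss would give the same small range, so it was not tested. SPTY2D1, which has Spt2 among its synonyms as SPTLC2 has SPT2, fell by 0.34 on the log2 scale (SE 0.08, adjusted p = 0.00705; −0.46 after the correction, below which lay 217 of the 10686 genes of at least 5 CPM in the higher group), but a log2 fold change of −1 or lower is argued against by a lowest bound of −0.60. A smaller loss, a hairpin against another gene, a loss of protein without loss of RNA, an exchange of labels without such a loss of SPTLC2 RNA, and a mix-up with samples from outside remain open.

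Median fold changes were below 0 in genes with high GC content and above 0 in those with low GC content. A technical source, GC-dependent differences between single libraries, may contribute, since libraries of the same group also differed along GC content, with Spearman correlations across genes of 0.24 in shControl (replicate 2 minus 1) and −0.28 in shSPTLC2. Of the lower calls 79.0% (928 of 1174) were in the 3 most GC-rich of the 10 parts, and of the higher calls 87.1% (478 of 549) in the 4 most GC-poor. A part of the trend that came with the hairpin is confounded with the groups and stays open as untested.

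The unfolded protein response and cholesterol synthesis lists were called lower in the libraries labelled shSPTLC2. The GC and length trend as the whole cause is argued against by the medians after its removal, −0.31 and −0.34, both still called by camera. A single library deciding both lists is argued against by the fits with each library left out, with and without the correction. Their highest median over both lists was −0.25. With an estimated correlation neither list was called (adjusted p = 0.144 each, and 0.169 and 0.166 after the correction). That form of camera rests on few degrees of freedom. Fry, run without the correction only, called both lists by direction (adjusted p = 0.0287 and 0.034). It called 9 lists by direction, among them MHC class I antigen presentation (fry adjusted p = 0.0287), whose camera call ended after the correction. The fry calls therefore do not set these 2 lists apart and do not bear on the GC and length trend. A difference in culture conditions between the groups and an effect of the hairpin stay open as untested, and the SPTLC2 RNA gives no sign of the labelled knockdown to tie them to.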
